A study of Mus musculus with 23 samples.

How the data were processed

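Total RNA from mesenteric arteries of male C57BL/6J mice, 10 to 12 weeks old, was sequenced. Angiotensin II (Ang II), the pressor peptide of the renin-angiotensin system, was given under the skin by osmotic minipump. The dose was 1000 ng per kg and minute and the infusion lasted 7 or 14 days, and control mice had sham surgery. Arteries were cleaned of fat and veins in an RNA-stabilising solution, and 500 ng of DNase-treated RNA entered a stranded total RNA library, per the labels' protocols. There were 23 libraries in 4 groups, with 6 libraries for sham at 7 days, 6 for Ang II at 7 days, 6 for sham at 14 days and 5 for Ang II at 14 days. Each library came from its own animal, as the animal numbers in the table header show, per the file headers.

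The authors deposited 1 table of normalized values, an expression signal per gene and library, with 39179 Ensembl gene identifiers and their symbols. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, FastQC, STAR 2.3.1, HTSeq 0.5.3p3, R 3.2.3 and edgeR 3.6.8, and the genome build was mm10. The gene annotation, the strand setting of the counting and the normalization method are not given in the sources used here. Because the strand setting is not stated, values of genes that overlap a gene on the other strand are uncertain. Values of near-identical gene copies (the elastases, trypsins and amylases, the Reg family, the globins, Agtr1a with Agtr1b) are uncertain as well, since reads may be divided between copies.

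The design fixed for the tests assumed gene counts and an edgeR test on them, with limma on log values as its stated fallback. The table held another unit, normalized signal values, so the design was kept as written and the fallback became the main test. In every library each of the 460324 values above 0 was a whole multiple of that library's smallest value, and 100% came out whole within a tolerance of 0.001 read. The values were thus gene read counts divided by a factor per library, and whole reads were recovered by taking the smallest value as 1 read. Library totals recovered in this way ran from 4471038 to 21509283 reads. The count test on recovered reads was run as an added alternative. Of the genes in the table, 12787 were at 0 in every library.

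Fold changes and tests were computed on log2(value + 0.5) with limma 3.58.1 in R 4.3.3, using the trended and robust empirical Bayes fit. A gene was tested when at least 5 libraries had a value of 1 or more, which left 14896 genes. All 23 libraries entered one fit with 4 group means. The contrasts were Ang II against sham at 7 days, Ang II against sham at 14 days, the difference of the responses at the 2 times, and 14-day against 7-day sham. The p-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. A fold change on this scale understates the change of genes with low values. The 2 comparisons of Ang II with sham shared no libraries, whereas the difference of the responses and the comparison of the sham groups used the same libraries again.

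Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. They were tested again with the correlation estimated from the data, and with fry. The 38 lists covered the extracellular matrix, smooth muscle, vasoactive and renin-angiotensin components, oxidant enzymes, growth factor signalling, proliferation, protein folding, inflammation, metabolism, the imprinted Dlk1-Dio3 locus, ETS transcription factors, and markers of other cells and of handling. The neutrophil and skeletal muscle marker lists had fewer than 5 measured members and were not tested, which left 36. Properties of single libraries were compared by an exact two-sided permutation test, with Benjamini-Hochberg adjustment over 21 measures per time.

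The genes named were fixed by rule. The rule took 15 genes whatever their result, the 8 genes with the largest rise and the 8 with the largest fall per time among called genes with a mean value of at least 1, and up to 4 members of each called list by smallest p. Genes outside the rule are said to have been chosen after their values were seen. The groups, tests, lists, named-gene rule and most of the alternatives were fixed before the data were examined.

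Coordinates and gene types come from GENCODE release M21 on GRCm38, which is the mm10 assembly. Of the 39179 identifiers 37607 were found there, and of the 14896 tested genes 14759 were found.

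The tests were run on simulated counts drawn from the mean, spread and library totals of the real data, with 200 genes changed in the Ang II group. At 7 days, over 14804 genes, 43.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 87.9% of those changed 3-fold were called, with 2 false calls among 144. At 14 days, over 14799 genes, the shares were 43.3%, 70.1% and 87.9%, with 3 false calls among 137. Simulated data with no change gave 0 calls over 14784 genes in each contrast. In a simulation that shifted the fibrillar collagen list 1.5-fold, that list alone was called among 36. Simulated genes varied independently of one another, so these runs do not show how the tests behave where genes of a list vary together.

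Replicates of a group were compared before averaging. All 55 pairs differed by more than sampling noise, with a lowest chi-square per degree of freedom of 9.58, so no library was counted as a copy of another. Correlations of pairs across genes ran from 0.918 to 0.990.

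The alternatives tried were other scalings of the recovered reads, DESeq2 1.42.0, limma voom, edgeR 4.0.16, other filters and pseudocounts, a 1.5-fold minimum, fits on the groups compared alone, the series of the number in the sample titles (its first 2 digits) as a covariate or without its series-30 libraries, and an adipocyte covariate. Each library was left out in turn. After the data were seen, covariates for pancreatic acinar genes, neuron genes and the clock phase were added, as were a fit without 5 libraries rich in neuron transcripts, a fit on thinned reads, a fit with pairs of neighbouring title numbers as a block and a fit with the log2 share of AY036118 as a covariate. The title series are labels whose meaning the labels do not state. A filter at 1 CPM coincided with the main filter and was not run apart. Some gene results are not reported here.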

Results

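Mesenteric arteries, the resistance vessels that supply the gut, were profiled by total RNA sequencing in mice infused with Ang II or sham-operated for 7 or 14 days. The libraries held 4471038 to 21509283 reads. The means were 8898834 ± 4893066 reads for sham (SD, n = 6) and 13848268 ± 4742944 for Ang II (n = 6) at 7 days. At 14 days they were 14214829 ± 3713039 for sham (n = 6) and 18587447 ± 2498606 for Ang II (n = 5). Depth was higher in the infused group at both times, without passing the exact permutation test (p = 0.097 and 0.058, adjusted p = 0.26 and 0.20 over 21 measures). Between 17381 and 21270 genes had at least 1 read in a library. All libraries held transcripts of tissue next to the arteries. The pancreatic lipase gene Pnlip lay between 7014 and 40212 on the authors' scale. A list of pancreatic acinar and gut epithelial markers, called the acinar list or acinar markers here, took 5.08% to 14.4% of reads. A single transcript listed as AY036118 took between 0.0431% and 36.2% of the reads, with the highest share in sham_7d replicate 5. Its mean share was lower with Ang II at both times, at 5.75 ± 5.22% against 15.9 ± 12.5% in sham at 7 days (SD, n = 6 each) and 0.367 ± 0.349% (n = 5) against 4.42 ± 3.93% (n = 6) at 14 days. The exact permutation p, a test added after the shares were seen, was 0.078 and 0.050 on the shares and 0.39 and 0.0065 on their log2 values.

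The first comparison asked which genes differed between Ang II and sham arteries after 7 days. The main change was a rise of extracellular matrix and cell division genes. Postn, which encodes the matricellular protein periostin, rose from 289 ± 28.6 to 642 ± 93.2 (SD, n = 6 each), a log2 fold change of 1.15 ± 0.13 (SE; limma, adjusted p = 3.5e-05). Col1a1 and Col3a1, the main fibrillar collagen genes, rose from 378 ± 121 to 983 ± 269 and from 1181 ± 273 to 2844 ± 700. Mki67, a marker of dividing cells, rose from 11.5 ± 3.21 to 30.7 ± 6.63. Each of the 4 genes was higher in all 6 infused libraries than in any 7-day sham library. In all, 112 genes were higher and 10 lower among 14896 tested at a limma adjusted p under 0.05, and 119 of these 122 were protein coding. A change of at least 2-fold was seen in 42 of the higher genes and 1 of the lower ones.

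The 18 genes of the fibrillar and associated collagen list all had positive fold changes at 7 days, with a median log2 of 0.71. Of these, 11 rose over all genes tested and 14 when adjusted over the list alone (camera adjusted p = 2.3e-25, and adjusted p = 0.0080 with an estimated correlation). Col3a1 rose by 1.27 on the log2 scale, Col5a2 by 0.90 and Col14a1 by 0.60. In the elastic fibre list 8 of 18 genes rose (9 adjusted over the list alone), among them elastin itself, Eln (log2 1.15), its assembly factor Fbln5 (0.75) and Mfap4 (0.99). The elastic fibre list had a median of 0.40 and an adjusted p of 2.4e-14, and an adjusted p = 0.019 with an estimated correlation. Enzymes that process and crosslink collagen rose together, with 8 of 24 called, 18 adjusted over the list alone, and a median of 0.44 (adjusted p = 1.4e-22, and adjusted p = 0.0080 with an estimated correlation). Among them were the procollagen peptidase Adamts2 (1.03), lysyl oxidase Lox (0.91) and the lysyl hydroxylase Plod2 (0.71).

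Matricellular and adhesive glycoproteins rose as a list at 7 days, with 5 of 22 members called and 8 adjusted over the list alone (median 0.48, adjusted p = 2.4e-12, and adjusted p = 0.0080 with an estimated correlation). Cilp rose by 1.36, Wisp1 by 0.98 and Igfbp7 by 0.67. In the proteoglycan list 3 of 20 genes rose, Vcan (0.72), Lum (1.00) and Bgn (0.75), and 4 when adjusted over the list alone (median 0.18, adjusted p = 2.4e-05, and adjusted p = 0.026 with an estimated correlation). Matrix proteases and their inhibitors rose as a list (median 0.30, adjusted p = 1.7e-08, and adjusted p = 0.019 with an estimated correlation). None of its 27 members was called by limma over all genes, though 8 were when adjusted over the list alone. The closest was Timp1, an inhibitor of matrix metalloproteinases, with a log2 fold change of 1.44 and an adjusted p of 0.054. Basement membrane genes had 2 of 21 members called, Sparc (0.99) and Col4a5 (0.49), and 8 adjusted over the list alone. The basement membrane median was 0.25 (adjusted p = 1.6e-08, but adjusted p = 0.20 with an estimated correlation).

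All 38 measured cell cycle genes had positive fold changes at 7 days. Of these, 13 rose and 28 did when adjusted over the list alone (median 0.74, adjusted p = 6.4e-34, and adjusted p = 0.0080 with an estimated correlation). The mitotic genes Kif20a, Cenpf and Prc1 rose by 1.42, 1.45 and 1.37. Knstrn and Ckap2l, which act at the mitotic spindle, were among the 8 largest rises (1.54 and 1.48). The largest rise by fold was that of Igfbp2, an insulin-like growth factor binding protein, from 7.02 ± 2.46 to 35.2 ± 22.1 (log2 2.12 ± 0.30, SE). It was followed by Dio2, which activates thyroid hormone, from 12.0 ± 3.94 to 48.9 ± 12.2 (2.01 ± 0.22), and Ltbp2, which binds elastic microfibrils (1.67 ± 0.33). In mm10 coordinates Postn lies at chromosome 3, 54361109 to 54391037, Col1a1 at chromosome 11, 94936224 to 94953042, Igfbp2 at chromosome 1, 72824503 to 72852474, and Dio2 at chromosome 12, 90724552 to 90738438. These spans run over the whole annotated genes, exons and introns included.

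The genes that fell at 7 days were few. Nrip2 fell by 0.75 on the log2 scale (25.8 ± 4.02 to 15.2 ± 2.78) and Klhl38 by 0.86, and both were lower in all 6 infused libraries than in any sham library. Xkr4 fell by 0.75, Armc3 by 0.75 and Ido1, an enzyme of tryptophan breakdown, by 0.84. Cytl1 fell by 0.58 and the mitochondrial kinase gene Pink1 by 0.36.

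**Figure D1:**
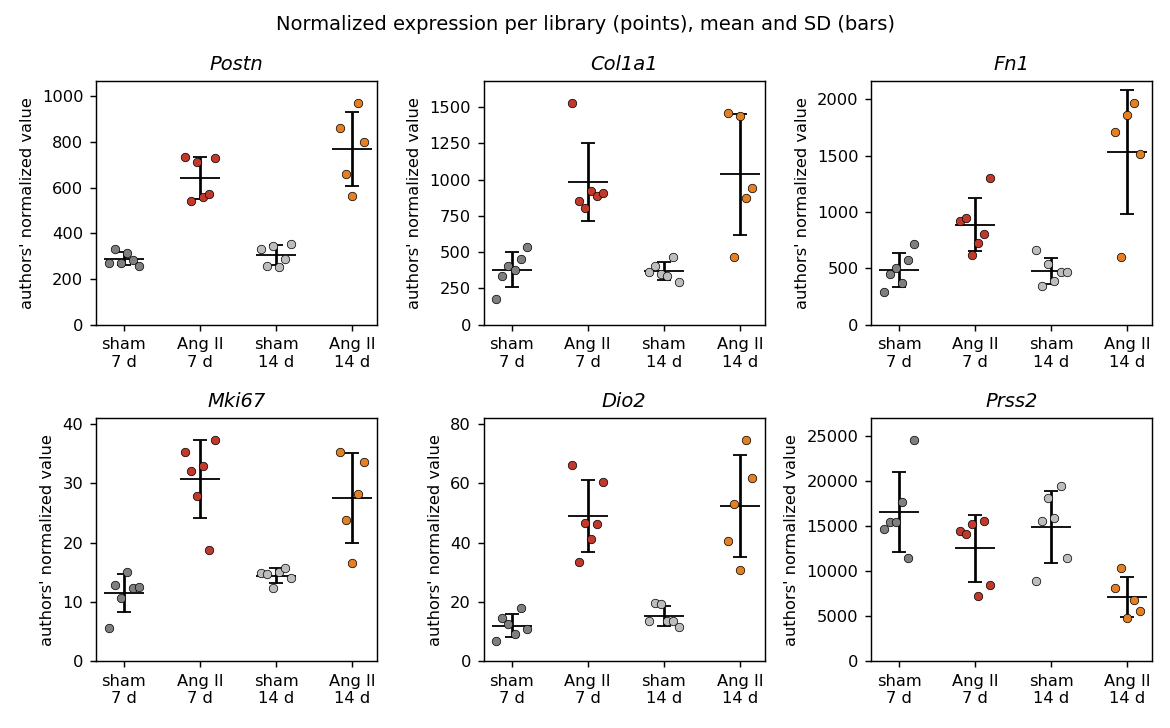
Authors' normalized value of 6 genes in each library (points), with the mean (horizontal bar) and SD (whiskers) of each group; each axis starts at 0. Postn, Mki67 and Dio2 were higher in all 6 infused libraries than in any sham library at 7 days, Fn1 reached its highest mean at 14 days (1530.2), and the pancreatic protease gene Prss2 had its lowest mean in Ang II at 14 days (7147).

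Markers of other cells also differed at 7 days. Fibroblast markers were higher as a list (median 0.19, 4 of 16 called and 5 adjusted over the list alone, adjusted p = 1.6e-05), but with an adjusted p = 0.20 with an estimated correlation. The called members were Pi16 (0.78), Col14a1, Lum and Mfap5 (0.67), and 3 of these 4 also stood in a matrix list. Macrophage and monocyte markers were higher as a list (median 0.36, adjusted p = 1.3e-05, and adjusted p = 0.40 with an estimated correlation) with 0 of 22 members called by limma over all genes and 1 adjusted over the list alone. The most significant member, Mrc1, had a log2 fold change of 0.49 and an adjusted p of 0.088. Interferon response genes were lower as a list (median -0.21, adjusted p = 2.4e-05, and adjusted p = 0.53 with an estimated correlation), with Gbp2 at -0.43. Acinar markers were lower (median -0.37, adjusted p = 0.0010, and adjusted p = 0.50 with an estimated correlation), and erythroid markers were higher (median 0.40, adjusted p = 0.036, and adjusted p = 0.63 with an estimated correlation). Lists of chemokines and cytokines (median 0.23, adjusted p = 0.027), of ER chaperones (0.14, adjusted p = 0.046) and of oxidative phosphorylation (-0.07, adjusted p = 0.033) were called as well. Their adjusted p-values were 0.55, 0.78 and 0.80 with an estimated correlation, and none of their members was called over all genes or over the list alone.

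The receptor and contractile genes that were followed whatever their result did not pass the test at 7 days. The Ang II receptor genes Agtr1a and Agtr1b had log2 fold changes of -0.44 ± 0.42 and -0.10 ± 0.20 (SE), and 0.03 without sham_7d replicate 1 and 0.01 without AngII_7d replicate 1. The smooth muscle genes Acta2 and Myh11 had 0.07 ± 0.14 and -0.13 ± 0.15, and the contractile list was not called (median 0.05, adjusted p = 0.19). Edn1 (0.22), Nos3 (0.08), Ccl2 (0.26), Ets1 (0.11) and the imprinted transcript Meg3 (-0.12) were not called by limma, with adjusted p between 0.76 and 0.95. Their signs, too, leaned on single libraries: without sham_7d replicate 1 Meg3 had 0.14, Nos3 -0.01 and Acta2 -0.03, and without AngII_7d replicate 4 Ccl2 had -0.14. Fn1 and Tnc had 0.89 ± 0.26 and 0.80 ± 0.33, with adjusted p of 0.12 and 0.40.

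In total, 16 lists were called at 7 days and 7 of them with an estimated correlation: the fibrillar collagen, elastic fibre, matricellular, proteoglycan, collagen processing, matrix protease and cell cycle lists. At an unadjusted p under 0.05 there were 1383 genes, where chance gives 745 for independent genes. The comparison of 14-day with 7-day sham, with no drug in either group, gave 1128. The 112 higher genes became 74 without sham_7d replicate 1, 64 without AngII_7d replicate 1 and 62 without AngII_7d replicate 6. The 10 lower genes became 4 without AngII_7d replicate 1 and 6 without AngII_7d replicate 6. In the title series that held both groups, the mean collagen list difference was 0.82 in series 27 and 0.55 in series 28, and that of the cell cycle list was 0.84 and 0.55.

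**Figure D2:**
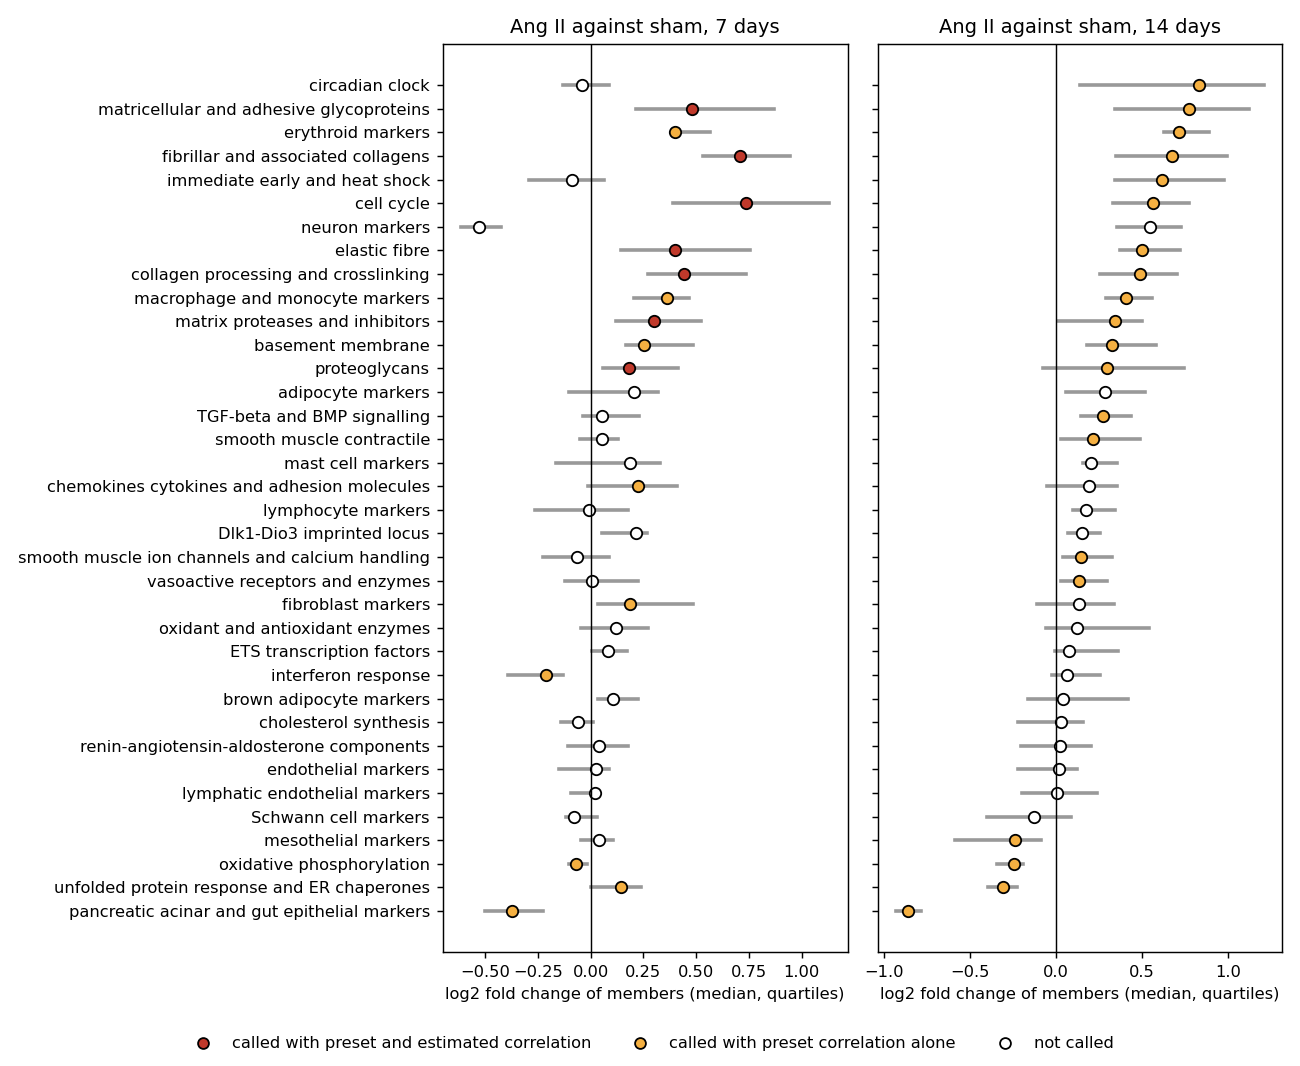
Median log2 fold change (points) and quartiles (bars) of the members of the 36 gene lists tested, for Ang II against sham at 7 days (left) and 14 days (right). Red marks the 7 lists called with both the preset and the estimated correlation, orange those called with the preset correlation alone, and white those not called; 16 lists were called at 7 days and 20 at 14 days.

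The second comparison asked the same of 14 days of infusion, where more genes passed the test. The matrix genes stood high here too. Postn rose from 304 ± 43.8 (SD, n = 6) to 771 ± 161 (n = 5), a log2 fold change of 1.32 ± 0.13 (SE; limma, adjusted p = 6.3e-06). Fn1, which encodes fibronectin, rose from 479 ± 114 to 1530.2 ± 548 (1.60 ± 0.27) and Tnc, tenascin C, from 19.5 ± 6.36 to 74.0 ± 45.0 (1.79 ± 0.34). The pancreatic genes Spink3 and Reg1 fell by 1.33 and 1.30, and the clock gene Arntl by 1.87. By limma 602 genes were higher and 300 lower among 14896 tested, 51 and 38 of them by at least 2-fold, and 868 of the 902 were protein coding. At an unadjusted p under 0.05 there were 3663 genes. The share of higher genes among the calls was 66.7% on the authors' scaling and 53.5% with upper-quartile scaling (422 higher, 367 lower). The counts leaned on single libraries: they were 393 higher and 151 lower without sham_14d replicate 2, 359 and 143 without replicate 3, 373 and 149 without replicate 4, and 398 higher without sham_14d replicate 6. Leaving out AngII_14d replicate 2 gave 1410 higher and 783 lower, replicate 3 gave 341 and 76, replicate 4 gave 283 and 116, and replicate 5 gave 320 and 124.

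Of the 20 lists called at 14 days none was called with an estimated correlation, where the 36 adjusted p-values started at 0.10. Of the 20, fry called 14, and it also called the ETS factors, which camera did not. Fibrillar collagens had a median log2 fold change of 0.67, with 11 of 18 higher and 14 adjusted over the list alone (camera adjusted p = 1.4e-09, and adjusted p = 0.17 with an estimated correlation). Col12a1 rose by 1.23, Col8a1 by 1.15, Col1a1 by 1.39 and Col3a1 by 1.02. Matricellular genes had 10 of 22 higher and 2 lower, with 15 and 2 adjusted over the list alone (median 0.78, adjusted p = 2.0e-08, and adjusted p = 0.10 with an estimated correlation). The TGF-beta target Ctgf rose by 1.27 and the cartilage matrix gene Comp by 1.81. Comp stood far higher in AngII_14d replicate 1 (29.5) than in the other infused libraries (7.43 to 10.2). Elastic fibre genes had 8 of 18 higher, and 12 higher and 1 lower adjusted over the list alone (median 0.50, adjusted p = 7.0e-08, and adjusted p = 0.17 with an estimated correlation). Ltbp2 showed the largest rise of the comparison, from 14.97 ± 3.17 to 101 ± 74.0 (2.44 ± 0.35, SE), and Eln rose by 0.99. Collagen processing genes had 13 of 24 higher and 16 adjusted over the list alone (median 0.49, adjusted p = 7.4e-10, and adjusted p = 0.17 with an estimated correlation). The heparan sulfatase Sulf1 rose from 114 ± 8.03 to 185 ± 16.7 (0.69 ± 0.08, SE) and Lox by 0.82.

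Basement membrane genes had 7 of 21 higher at 14 days (9 adjusted over the list alone, median 0.33, adjusted p = 4.2e-05, and adjusted p = 0.34 with an estimated correlation), with Sparc at 0.90. Proteoglycans had 7 higher and 1 lower of 20, and 9 and 2 adjusted over the list alone (median 0.30, adjusted p = 0.0097, and adjusted p = 0.24 with an estimated correlation). Among them the aggrecan gene Acan rose by 2.13 from a low level and Bgn by 1.15. Proteases and inhibitors had 7 of 27 higher, and 13 higher and 2 lower adjusted over the list alone (median 0.34, adjusted p = 4.2e-04, and adjusted p = 0.20 with an estimated correlation). Timp1 rose by 1.45 and Mmp2 by 0.79. Both stood highest in AngII_14d replicate 1, with Timp1 at 85.3 (other infused libraries 12.7 to 25.8) and Mmp2 at 337 (176 to 222). Cell cycle genes had 11 of 38 higher and 19 adjusted over the list alone (median 0.56, adjusted p = 2.1e-09, and adjusted p = 0.24 with an estimated correlation). Kif20a rose by 1.14 and Mki67 by 0.86.

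Smooth muscle and signalling lists were called at 14 days. Of the 25 contractile genes 6 were higher and 9 adjusted over the list alone (median 0.22, adjusted p = 0.0017, and adjusted p = 0.52 with an estimated correlation). They included the actin-binding genes Cald1 (0.49), Vcl (0.53) and Actn1 (0.93), whereas Acta2 and Myh11 had 0.20 ± 0.14 and 0.22 ± 0.15 (SE) and were not called. Of the 30 ion channel and calcium handling genes 3 were higher and 1 lower, and 6 and 1 adjusted over the list alone (median 0.15, adjusted p = 0.015, and adjusted p = 0.34 with an estimated correlation). The KATP channel subunit Abcc9 rose by 0.82 and Pln, an inhibitor of the calcium pump, fell by 0.88. TGF-beta and BMP signalling genes had 7 of 30 higher and 12 adjusted over the list alone (median 0.27, adjusted p = 1.0e-05, and adjusted p = 0.17 with an estimated correlation), with Gdf6 at 1.08, Bmp2 at 0.64 and Tgfb2 at 0.65. Vasoactive receptors and enzymes had 3 of 34 higher, and 6 higher and 1 lower adjusted over the list alone (median 0.14, adjusted p = 0.029, and adjusted p = 0.37 with an estimated correlation). These 3 were the prostacyclin synthase Ptgis (0.59), the serotonin receptor Htr2a (0.77) and the endothelin receptor Ednra (0.43).

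Lists lower at 14 days were those of oxidative phosphorylation, ER chaperones, mesothelial markers and acinar markers. Oxidative phosphorylation had 7 of 34 genes lower and 10 adjusted over the list alone (median -0.25, adjusted p = 1.2e-10, and adjusted p = 0.30 with an estimated correlation). Ndufb8 fell by 0.50, Cox6c by 0.47 and Atp5o by 0.41. None of the 23 genes of the unfolded protein response and ER chaperone list was called by limma over all genes or over the list alone (median -0.31, adjusted p = 4.7e-06, and adjusted p = 0.34 with an estimated correlation); Xbp1 had -0.25 and Sdf2l1 -0.80. Mesothelial markers had a median of -0.24 with 0 of 9 called over all genes or over the list alone (adjusted p = 0.016, and adjusted p = 0.38 with an estimated correlation). Acinar markers had 9 of 14 lower and 12 adjusted over the list alone (median -0.86, adjusted p = 1.4e-09, and adjusted p = 0.17 with an estimated correlation). Prss2 fell from 14888 ± 4004 to 7147 ± 2180 (SD), and Reg3d, another pancreatic gene, fell by 1.71.

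Of 21 measures of the libraries compared at 14 days, 1 passed the test. The 10 most abundant genes took 25.5 ± 3.66% of reads in Ang II (n = 5) and 35.7 ± 2.69% in sham (n = 6; exact permutation p = 0.0022, adjusted p = 0.045 over 21 measures). The acinar share of reads was 6.87 ± 1.39% and 10.9 ± 2.89% (exact permutation p = 0.030, adjusted p = 0.16), which did not pass. With the mean of the acinar list as a covariate, 5 genes were higher and 0 lower by limma at 14 days. The 5 genes were Dio2, Sulf1, Serpine2, Postn and Fam46a, the last chosen after its values were seen. Their log2 fold changes in that fit were 1.87, 0.70, 0.93, 1.22 and 0.88. As the genes still called, they do not speak for the rest. At an unadjusted p under 0.05 that fit gave 1418 genes. With the title series as a covariate 14 were higher and 2 lower; the 14-day groups overlapped in series 26 alone, where the mean collagen list difference was 0.70, the oxidative phosphorylation difference -0.29, the acinar difference -0.81 and the ER chaperone difference -0.12, where all 14-day libraries gave -0.30 for the chaperones. With the log2 share of AY036118 as a covariate 322 genes were higher and 106 lower at 14 days.

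Genes of the circadian clock differed between the 14-day groups in opposite directions. Arntl fell from 22.2 ± 11.3 (SD, n = 6) to 6.36 ± 6.42 (n = 5) and Npas2 by 1.66 on the log2 scale. Per3 rose from 34.7 ± 21.1 to 96.0 ± 34.3, Hlf by 1.70 and Bhlhe41 by 1.21. Of the 18 clock genes 6 were higher and 3 lower, and 11 and 3 adjusted over the list alone (median 0.83, adjusted p = 0.012, and adjusted p = 0.25 with an estimated correlation). The clock list was not called without the series-30 libraries. An arm difference was taken as the mean log2 value of 9 output and repressor genes minus that of 4 genes set against them. The 4 were the activators Arntl, Clock and Npas2, and Nfil3. At 14 days the arm difference was 2.88 ± 1.30 (SD, n = 5) in Ang II and 0.60 ± 1.36 (n = 6) in sham (exact permutation p = 0.028). It was above 2 in 4 infused libraries and in sham_14d replicate 2. With this arm difference as a covariate 225 genes were higher and 35 lower at 14 days. Immediate early genes were higher as a list in the same comparison (median 0.62, 1 of 23 called and 5 adjusted over the list alone, adjusted p = 9.0e-04, and adjusted p = 0.47 with an estimated correlation), with Ier3 at 0.62 and Junb at 1.11, the latter not called.

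**Figure D3:**
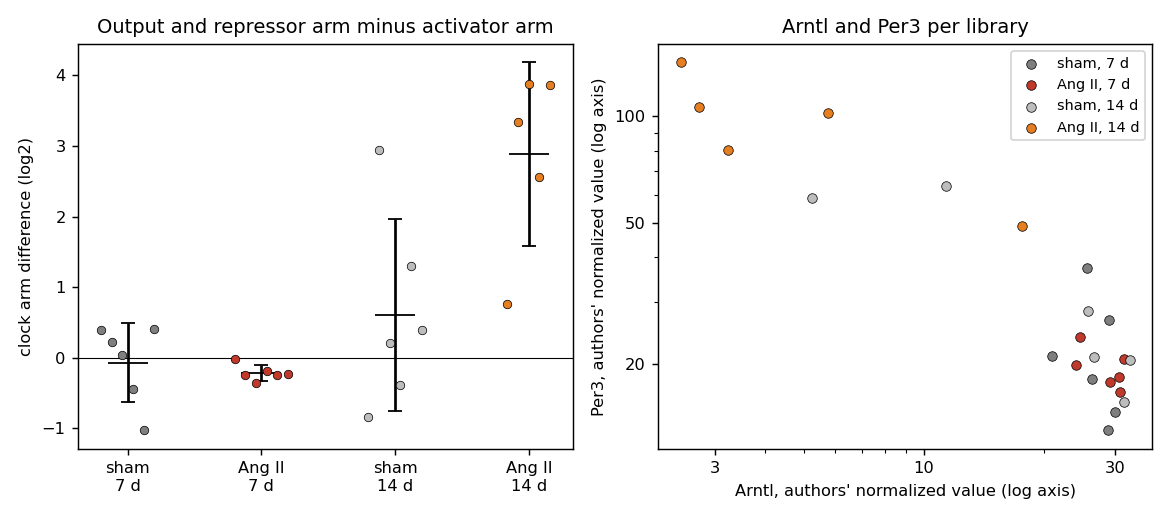
Left, clock arm difference per library, with group mean and SD. It is the mean log2 value of 9 output and repressor genes minus that of 4 genes (the activators Arntl, Clock and Npas2, and Nfil3). Right, authors' normalized values of Arntl and Per3 per library on log axes; the 14-day libraries spread from Arntl 32.8 down to 2.46, while the 7-day libraries stayed between 20.9 and 31.7.

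Among blood and immune cells at 14 days, macrophage markers were higher as a list (median 0.41, 1 of 22 called and 5 adjusted over the list alone, adjusted p = 2.4e-04, and adjusted p = 0.40 with an estimated correlation), with the growth factor receptor Csf1r at 0.62. Erythroid markers were higher as a list (median 0.72, adjusted p = 0.045, and adjusted p = 0.61 with an estimated correlation) with 0 of 7 called over all genes or over the list alone. Agtr1a (0.22 ± 0.44, SE), Agtr1b (0.01 ± 0.21), Edn1 (0.07), Nos3 (0.03), Ccl2 (0.17), Ets1 (0.07) and Meg3 (0.51) were not called by limma at 14 days. The signs of the first 5 turned when single libraries were left out, Ccl2 to -0.30 without AngII_14d replicate 1 and Agtr1a to -0.04 without AngII_14d replicate 3. Dio2 and Igfbp2 rose by 1.70 and 2.16, and Kif26b by 1.63. Kif26b also stood out in libraries rich in neuron transcripts: sham_7d replicate 1 (17.2), AngII_7d replicate 1 (10.1) and sham_14d replicate 1 (5.17). AngII_14d replicates 1 and 3 were rich in neuron transcripts too (list means 4.71 and 5.19). With the neuron list as a covariate, 0 of 102 named gene results at 14 days lost their call or turned sign. Kif26b was among the 102. This argues against neuron content as the whole cause of the Kif26b call, though it may add to the size of the rise. Genes of low level that fell were Ranbp3l (by 1.70), Trim50 (by 1.40) and Marc1 (by 1.35).

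Lists that camera called at neither time covered the renin-angiotensin components, whose medians were 0.04 at 7 days (adjusted p = 0.65) and 0.03 at 14 days (mean -0.02, direction down, adjusted p = 0.46). Oxidant and antioxidant enzymes had 0.12 and 0.12 (adjusted p = 0.071 and 0.14), the ETS factors 0.08 and 0.07 (0.056 and 0.087, but fry adjusted p = 0.011 at 14 days), and the imprinted Dlk1-Dio3 locus 0.22 and 0.15 (0.30 and 0.49). Cholesterol synthesis genes had -0.06 and 0.03 (0.20 and 0.51), with a mean of -0.01 and direction down at 14 days. Endothelial markers had 0.03 and 0.02 (0.49 and 0.33), with means of -0.02 and -0.03 and direction down. Lymphatic endothelial markers had 0.02 with a mean of -0.02 at 7 days and 0.00 with a mean of 0.03 but direction down at 14 days (0.76 and 0.87). Lymphocyte markers had -0.01 and 0.17 (0.62 and 0.49), mast cell markers 0.18 and 0.20 (0.87 and 0.46), and Schwann cell markers -0.08 and -0.13 (0.65 and 0.14). Adipocyte markers had 0.21 and 0.29 (0.46 and 0.44), and brown adipocyte markers, which include Dio2, had 0.11 and 0.04 (0.054 and 0.42). Neuron markers had -0.53 and 0.55 (0.055 and 0.44) and were highest in sham_7d replicate 1. At 7 days alone, the ion channel (-0.06, 0.27), TGF-beta (0.05, 0.061), vasoactive (0.01, 0.77), mesothelial (0.04, 0.76), clock (-0.04, 0.79) and immediate early (-0.09, 0.083) lists were not called. At 14 days alone, the chemokine (0.19, 0.31), interferon (0.06, 0.38) and fibroblast (0.13, 0.25) lists were not called. Some members of these lists were called by limma all the same. At 7 days these were 1 contractile, 1 oxidant enzyme and 1 brown adipocyte gene, all higher, and 1 higher and 1 lower TGF-beta gene. Adjusted over each list alone, 2 ion channel and 2 vasoactive genes were higher and 1 of each lower, and 1 endothelial and 2 immediate early genes were lower, beside the same numbers in the lists just named. At 14 days 2 of 18 ETS, 3 of 16 fibroblast, 2 of 26 chemokine, 1 oxidant enzyme and 1 brown adipocyte gene were higher, and 1 chemokine and 1 renin-angiotensin gene were lower. Adjusted over each list alone, 6 ETS, 4 fibroblast, 3 chemokine, 3 oxidant enzyme and 1 brown adipocyte gene were higher, and 1 ETS, 2 fibroblast, 1 chemokine and 1 renin-angiotensin gene were lower. The untested neutrophil and skeletal muscle lists had mean differences of 0.12 and 0.45 at 7 days (exact permutation p = 0.81 and 0.011, adjusted p = 0.89 and 0.076) and of 0.04 and -0.01 at 14 days (exact permutation p = 0.97 and 0.98).

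The third comparison set the responses at the 2 times against each other. Over all 14896 genes, which are not independent replicates, the fold changes at 7 and 14 days had a Pearson's r of 0.31 ± 0.20 (jackknife SE over libraries) and a Spearman's rho of 0.27. Leaving out single libraries moved r between 0.25 and 0.44. With that SE a correlation of 0 is not excluded. The 2 sets of higher genes shared 77, where 4.53 were expected of independent lists, and the sets of lower genes shared 4, where 0.20 were expected. Of the 112 genes higher at 7 days, 111 had a positive fold change at 14 days. Of the genes called at 14 days, 519 of the 602 higher and 235 of the 300 lower had the same sign at 7 days. The median log2 fold change of the 602 was 0.59 at 14 days and 0.20 at 7 days.

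By limma 0 genes differed in their response between 14 and 7 days, with 1396 at an unadjusted p under 0.05. For independent genes chance gives 745, and the comparison of the sham groups gave 1128. The edgeR quasi-likelihood test on recovered reads gave 0 genes and DESeq2 gave 7. The 7, chosen after their values were seen, were Habp2, Npas2, Ceacam1 and Cd209g with a lower response at 14 days, and Ip6k1, Cpe and Gfod1 with a higher one. In limma the adjusted p of Cd209g, a C-type lectin, was 0.15. For Fn1 and Tnc, called at 14 days alone, the difference of responses was 0.70 and 0.99 on the log2 scale and did not pass. Camera called 12 lists for the difference, none of them with an estimated correlation and none by fry. The largest medians were those of clock genes (0.78, adjusted p = 0.0074, and adjusted p = 0.57 with an estimated correlation) and of neuron markers (1.04, adjusted p = 0.047, and adjusted p = 0.98 with an estimated correlation). The neuron value rested on a few libraries, since it was 0.34 without sham_7d replicate 1 and -0.31 without the 5 neuron-rich libraries. The fibrillar collagen list had a median difference of -0.08 and was not called (adjusted p = 0.45).

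**Figure D4:**
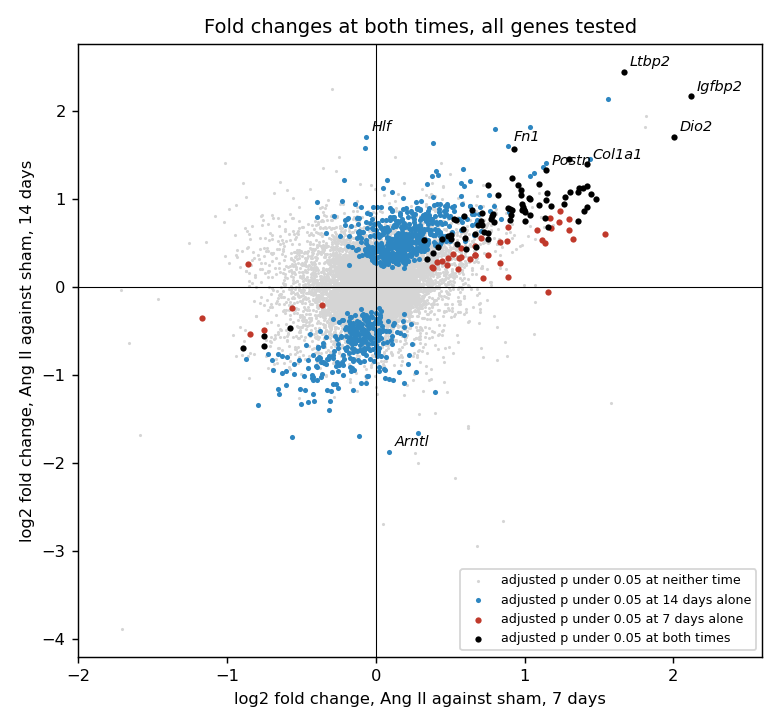
Log2 fold change of Ang II against sham at 7 days (horizontal) and 14 days (vertical) for the 14896 genes tested, coloured by the time at which the limma adjusted p was under 0.05. The 77 genes higher at both times lie in the upper right, with Postn, Col1a1, Dio2, Igfbp2 and Ltbp2 among them, while Arntl and Hlf lie near 0 at 7 days.

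The last comparison was between the sham groups, labelled as 7-day and 14-day sham. Of the 2 sham groups only that of 14 days held libraries of title series 26, so duration and title series were not fully separate. By limma 0 genes differed, with 1128 at an unadjusted p under 0.05, and the edgeR quasi-likelihood test gave 0. DESeq2 gave 1, Cd209g, which limma placed at a log2 difference of 0.88 and an adjusted p of 0.084. Without sham_7d replicate 2 limma gave 1 gene, 4930522L14Rik, chosen after its values were seen. No list was called by camera, and fry called 0. Arntl (-0.49) and Per3 (0.54) did not pass, and the clock list had a median of 0.12 and an adjusted p of 0.39.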

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

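The tests of the artery wall share and of the clock arms were chosen after the results were seen, as was the use of contractile genes against the acinar explanation. The test of the AY036118 share was added after the collagen and list results were seen, with its bound written before it was run. For the other tests below the deciding outcomes were written before each test was run. The acinar covariate itself was added after the data were seen. Explanations are weighed for the collagen, chaperone and clock patterns, and the rest are given as values.

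Fibrillar collagens were higher as a list with Ang II at both times by camera, with 11 of 18 genes called at each. With an estimated correlation the list call held at 7 days (adjusted p = 0.0080) and was lost at 14 days (adjusted p = 0.17). If less pancreatic acinar RNA were the cause, the rise would shrink once the acinar list is a covariate; it was 0.69 at 7 days (0.72 without; 95% interval 0.39 to 0.99) and 0.56 at 14 days (0.65 without; 0.13 to 0.98). The 7-day value excludes that explanation by the bound written before the test was run. At 14 days that bound alone left it open. If a larger share of artery wall were the cause, collagen and contractile genes would rise alike, but the collagen mean rose beyond the contractile mean by 0.64 at 7 days (0.36 to 0.93; exact permutation p = 0.0022) and by 0.39 at 14 days (0.09 to 0.69; p = 0.0065). That gap argues against either as the whole cause at both times, as far as each raises collagen and contractile genes alike. It cannot test a larger share of fibroblast-rich tissue alone, which would raise collagen beyond contractile genes and give the same gap. With the log2 share of AY036118 as a covariate the collagen rise was 0.75 at 7 days (0.46 to 1.04) and 0.72 at 14 days (0.38 to 1.06), above the bound of the acinar test, so the smaller share of that transcript in infused libraries is excluded as the whole cause. A response of matrix genes to the infusion, or a change in fibroblasts, remains a hypothesis.

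ER chaperone and oxidative phosphorylation lists were lower with Ang II at 14 days by camera, with 0 of 23 and 7 of 34 genes called. Both list calls were lost with an estimated correlation (adjusted p = 0.34 and 0.30). With the acinar covariate the differences were -0.023 (-0.30 without; -0.40 to 0.36) and -0.23 (-0.27 without; -0.53 to 0.08), and within groups the lists followed the acinar score with r of 0.46 (permutation p = 0.053) and 0.11 (p = 0.62). With depth as a covariate they were -0.28 (-0.59 to 0.04) and -0.28 (-0.51 to -0.06), and with the AY036118 share -0.25 (-0.59 to 0.10) and -0.30 (-0.55 to -0.05). With depth or the AY036118 share as a covariate, the oxidative phosphorylation difference did not shrink and its intervals stayed below 0. The intervals are still too wide to exclude that less acinar RNA, deeper sequencing or that share accounts for part of either list. An effect of Ang II stays open.

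Clock genes differed between the 14-day groups. The arm difference was 2.28 higher with Ang II (95% interval 1.06 to 3.50; exact permutation p = 0.028) and -0.15 at 7 days (-1.31 to 1.02; p = 0.56). Both intervals used 1 spread for all 4 groups. The SDs of sham and Ang II were 0.57 and 0.11 at 7 days, and 1.36 and 1.30 at 14 days. The interval is thus too narrow at 14 days and too wide at 7 days. Collection of the groups at different times of day may account for this, and collection times are not given in the sources used here. An effect of Ang II on the clock stays open and was not tested.

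Of 100 splits of the same libraries, the real one gave the most genes at 7 days (122 against a highest other of 0) and at 14 days (902 against 489). A random division of the libraries is thus unlikely to give such counts. The splits cannot exclude that the groups differed in acinar content, clock phase or title series. With the acinar list or the title series as a covariate, far fewer genes were called at 14 days, as given above. For the difference of the responses (0 against a highest other of 5) and for sham against sham (0 against 2) the real count was 0. All 100 splits then had to give as many, so these splits decide nothing. For these comparisons limma had 1396 and 1128 genes at an unadjusted p under 0.05, edgeR 0 and 0, and DESeq2 7 and 1.

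The difference of the responses at 14 and 7 days passed the camera test in 12 lists, none with an estimated correlation. The medians were 0.21 for contractile genes, 0.22 for ion channels, 0.25 for TGF-beta signalling, 0.37 for interferon genes, 1.04 for neuron markers, 0.78 for clock genes and 0.69 for immediate early genes. They were -0.21 for the cell cycle, -0.39 for ER chaperones, -0.17 for oxidative phosphorylation, -0.36 for mesothelial markers and -0.50 for acinar markers.

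Single libraries stood far from the rest of their group in 60 of 584 groups of values. For independent normal values about 1 in 20 groups would be flagged, which comes to 29.2. Most values here were unlogged and came from genes picked for the text, so that number is a rough guide and the excess was not tested. In sham_7d replicate 1 the neuron list mean was 6.49 on the log2 scale and the endothelial mean 5.39, with Agtr1a at 33.8 (others 3.90 to 5.36), Meg3 at 211, Kif26b at 17.2, Myh11 at 1203, Sulf1 at 95.3, Wisp1 at 9.73 and Marc1 at 0.625. AngII_7d replicate 1 had a neuron mean of 4.16, Agtr1a at 8.05, Kif26b at 10.1, Col1a1 at 1527, Comp at 15.7 and Pln at 30.2. Sham_14d replicate 1 had a neuron mean of 4.27, Kif26b at 5.17, Igf1 at 131 and Xbp1 at 125.

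In sham_7d replicate 6 the acinar mean was 11.2, with Pnlip at 40212, Spink3 at 545, Zg16 at 5840, Acan at 0.739, Bmp2 at 13.3, Htr2a at 4.68 and Ranbp3l at 5.66. Sham_7d replicate 4 had an adipocyte mean of 7.39 and Csf1r at 118. In sham_7d replicate 2 4930522L14Rik was at 9.55, and in replicate 5 Habp2 was at 9.77. AngII_7d replicate 4 had an acinar mean of 9.85, Ccl2 at 18.3, Timp1 at 44.5, Bhlhe41 at 10.4, Fam46a at 42.7 and Serpine2 at 109. AngII_7d replicate 5 had Fgf2 at 17.4, and replicate 6 had Gbp2 at 36.1, Habp2 at 11.9 and Pdgfc at 37.6.

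In AngII_14d replicate 1 Ccl2 was at 18.6, Comp at 29.5, Col5a2 at 673, Mmp2 at 337, Timp1 at 85.3 (others 12.7 to 25.8) and Arntl at 17.6. AngII_14d replicate 2 had Eln at 90.6 (others 213 to 250.1), Amy2b at 227 and Armc3 at 1.98. Replicate 3 had a Schwann cell mean of 3.74 and 4930522L14Rik at 5.22, and replicate 4 had Abcc9 at 182. Among sham libraries at 14 days, replicate 2 had Junb at 124, replicate 3 had Aqp8 at 5.89 and replicate 6 had Marc1 at 5.604. Sham_14d replicate 4 had Pln at 234, Igfbp7 at 367, Gxylt2 at 3.83 and Ckap2l at 1.83.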

How the results depend on the processing

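The design named edgeR on recovered reads as an added alternative for a table without counts. It named filterByExpr as the filter of its count test, and running limma with that filter was chosen after the data were seen. So were the acinar, neuron and clock covariates, the fit without 5 neuron-rich libraries, the thinned reads, the block of title numbers and the AY036118 covariate. The other alternatives were chosen before. At 7 days DESeq2 gave 173 higher and 39 lower genes, the title series as a covariate gave 6 lower, the acinar covariate 67 higher, and thinned reads 70 higher and 5 lower. At 14 days DESeq2 gave 1032 higher and 766 lower, voom 910 and 536, a minimum of 1.5-fold 302 and 167, and a fit on the groups compared alone 258 and 85. No filter gave 163 lower, over 26392 genes. The title series as a covariate gave 14 higher and 2 lower, a fit without the series-30 libraries 83 and 15, and the acinar covariate 5 and 0, with 1418 genes at an unadjusted p under 0.05. A fit without 5 neuron-rich libraries gave 269 and 77, the clock arm difference as a covariate 225 and 35, of which 168 and 29 were shared with the calls reported, thinned reads 269 higher, and the AY036118 share as a covariate 322 and 106. For the difference of the responses DESeq2 gave 7 genes and for sham against sham 1, where limma gave 0 and 0 and edgeR 0 and 0. With an estimated correlation 7 lists were called at 7 days and 0 at 14 days.

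With the acinar list as a covariate the signs of acinar results at 14 days turned, which follows from adjusting a list for itself: Cela3b had 0.026, Ctrl 0.098, Amy2b 0.061 and the acinar list 0.084, and 0.13 for the difference of responses. In the same way the neuron list had a difference of -0.066 with the neuron covariate, and without the neuron-rich libraries it had -0.43 at 14 days and -0.31 for the difference. The cause of the other changes was not tested, apart from fewer genes or samples where an alternative removed them.

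Leaving out 1 library at a time gave 62 to 145 higher and 4 to 14 lower genes at 7 days, 283 to 1410 higher and 76 to 783 lower at 14 days, 0 for the difference of the responses, and 0 to 1 for sham against sham. The lists called ran from 13 to 19 at 7 days and from 18 to 22 at 14 days, and the correlation of fold changes from 0.25 to 0.44. Other alternatives moved more of the 36 lists. At 14 days the acinar covariate lost 5 calls, gained 3 and turned the direction of 1. The clock covariate lost 6 and gained 5, and leaving out the series-30 libraries lost 6 and gained 3. At 7 days the acinar covariate lost 3 and gained 3, and leaving out the neuron-rich libraries lost 3 and gained 1. The edgeR test gave 109 higher and 10 lower genes at 7 days and 883 and 358 at 14 days. The labels pair no animals, and the replicate numbers were given in accession order. Neighbouring title numbers, up to 2 apart, joined 4 pairs of sham and infused libraries at 7 days and 2 at 14 days. Their deviations from the group means correlated by -0.34 to 0.45, above 0.1 in 3 of the 6 pairs, and 1 pair was the best match for each other, so the numbers were not taken as a pairing. With these pairs as a replicate block limma gave 101 higher and 13 lower genes at 7 days, 481 and 227 at 14 days, and 17 and 19 lists. The library of lowest depth held 4471038 reads, which may limit calls among genes of low level.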

Other observations

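The genes in this part were chosen after their values were seen, and no test was added for them. Igf1, a growth factor, rose from 89.2 ± 13.4 (SD, n = 6) to 169 ± 20.8 (n = 6) at 7 days, a log2 fold change of 0.92 (limma, adjusted p = 1.2e-04), and by 0.88 at 14 days. Piezo2, a stretch-activated channel, rose by 1.04 and 1.00, and both genes were higher in 6 of 6 and 5 of 5 infused libraries than in any sham library of the time. Csrp2 rose by 0.72 and 0.70, the endothelial gene Esm1 by 1.36 and 1.08, Scube3 by 0.93 and 1.57, and the TGF-beta target Pmepa1 by 0.65 and 0.87. Gxylt2, a glycosyltransferase gene, rose by 1.1 and 1.16.

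At 14 days the growth factor genes Fgf2, Pdgfc and Bdnf rose by 0.79, 0.65 and 1.14 (limma), the serotonin receptor Htr1b by 1.26, and the Wnt receptors Fzd1 and Fzd7 by 0.70 and 0.75. Angpt1, a ligand of the endothelial receptor Tek, fell by 0.62. The secretory and epithelial genes Aqp8, Zg16, Slc5a1 and Tmed6 fell by 1.30, 1.21, 1.00 and 1.19. The calcium channel gene Cacna1g rose by 0.89 at 7 days and had 0.12 at 14 days, and the difference of the responses did not pass the test (limma adjusted p = 0.51).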
